A study of Citrus trifoliata with 4 samples.

How the data were processed

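Small RNA was sequenced from an early-flowering mutant of trifoliate orange (Citrus trifoliata, a deciduous relative of the citrus fruit trees) and from its wild type. There were 4 libraries, 1 for each combination of genotype (wild type or mutant) and stage (juvenile or adult). Per the labels' protocols, juvenile material was shoot meristems taken in June, and adult material was lateral buds of spring shoots taken in April of the following year, although the tissue label reads shoot meristems for each sample. Stage is therefore confounded with organ, month and year, and these cannot be told apart here. The protocol names 3 individual plants as the source of the material and does not say whether their RNA was pooled. Each library is treated as 1 sample.

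Per the labels' protocols, RNA of 18 to 30 bases was cut from a polyacrylamide gel, ligated to adaptors at both ends, amplified by PCR, size-selected again and read on an Illumina Genome Analyzer. The deposited values are counts: each line gives the length of a unique sequence, the number of reads with it and the sequence itself, per the file headers and the series' format description. The authors removed low-quality reads, trimmed the adaptors, and set aside inserts shorter than 18 bases before collapsing identical reads; the trimming software and its version are not given in the sources used here, and neither is any aligner or genome build. No molecular identifiers were used, so reads are not independent molecules, and each interval given covers counting error only.

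The counts summed to 21478087 clean reads in the juvenile wild type, 17526615 in the adult wild type, 18364794 in the juvenile mutant and 17736041 in the adult mutant, equal to the totals in the deposited cleaning logs. Clean reads made up 97.5% to 98.6% of high-quality reads. About 75% of unique sequences were read once (74.6% to 76.3%), and these held 16.1% to 19.1% of reads. A library in which a family had no read was set to a floor of 3 reads for a ratio.

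No genome was used, so sequences were assigned to microRNA families and not to loci, and no coordinates are given. A set of 61 mature reference sequences in 48 families was written from general knowledge before the data were examined. Of these, 40 families were plant families that citrus was taken to hold, and 8 were controls: 4 Brassicaceae families, 1 of monocots and mosses, and 3 animal families. Members of 1 family share most bases, so reads were not split among its loci. A read of 19 to 24 nt was assigned where it could be placed without gaps with its 5′ end within 2 nt, its 3′ end within 3 nt and at most 2 mismatches to a reference. The reference with the fewest mismatches took the read, then the one with the smallest end offsets. The reversed references were matched in the same way as a measure of chance. A family counted as detected when its reads exceeded 3 times that background and numbered more than 3. On simulated reads the matching put 1334 of 1334 reads with up to 2 mismatches in the right family, placed 2 of 855 reads with more mismatches, and placed 0 of 20000 random reads. Opposite strands of hairpins were sought as reads that pair with the mature reference with at most 4 mismatches, leaving out reads already assigned. A set of animal microRNAs (6 arthropod, 6 vertebrate and 6 shared by both) was written after the data were first examined and matched with at most 1 mismatch. In the data all 40 plant families were detected by this rule, which is lenient because the reversed background was 0 for most families. It passed miR1446 with 8 reads, and also the controls miR529 and let-7, the latter with 239 reads at up to 2 mismatches. The 4 Brassicaceae controls together had 2 reads (all of miR158), and the monocot control miR529 had 10.

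Read counts were divided by the clean reads of the library and given as RPM (reads scaled to 1000000 clean reads). The 4 pairwise comparisons had 1 library per group, so they carry no replicate check and no p-value. Each is a log2 ratio with the exact (Clopper-Pearson based) 95% interval of the ratio of 2 Poisson counts. A family was measured in a comparison when it reached 10 RPM in at least 1 of the 2 libraries, and the summary is the number of measured families at 2-fold or more. The families named are those at 2-fold or more in a comparison, with miR156/miR157 and miR172 named in each comparison. Families were grouped in 8 lists written before the data were examined: phase change and flowering, auxin signalling, meristem and organ patterning, small RNA machinery, nutrient and copper homeostasis, resistance gene and phasiRNA triggers, MYB and phenylpropanoid, and citrus or woody lineage. A list's median was set against 10000 random lists of the same size matched on mean level in 3 bins.

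The only error that spans libraries is the genotype by stage interaction. It was used in an additive fit (genotype plus stage, 1 residual degree of freedom) with edgeR 4.0.16 in R 4.3.3: the quasi-likelihood test on raw counts, with total clean reads as library size and Benjamini-Hochberg adjustment at 0.05. The fit was run on 30 families with at least 10 RPM in at least 1 library. It was also run on 5452 sequences with at least 10 RPM in at least 2 libraries. It asks which families differed alike on both sides of the other factor, and its p-values rest on these 4 libraries alone. With 1 residual degree of freedom for each family or sequence, edgeR shares the spread across all those in the fit. A p-value therefore rests on this shared spread and not on replicates. Standard errors were the log2 fold change divided by the square root of F. In counts simulated for the stage effect on the 5452 sequences, 0 of 200 changes of 2-fold and 0 of 200 of 4-fold were called, and 198 of 200 of 16-fold, with 18 false calls at 16-fold. On the 30 families 198 of 200 changes of 16-fold were called, with 6 false calls. Smaller changes were not simulated on the families, so how well the fit finds them is not known. For the sequences the text names the 5 with the largest rise and the 5 with the largest fall among those called with a mean of at least 50 RPM.

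Alternatives were other scalings (edgeR TMM factors, plant-family reads, reads of 20 to 22 nt), stricter matching, other minimum levels, a pseudocount, DESeq2 1.42.0, fits without the covariate and a relaxed low-count filter. Scaling to reads outside miR156/miR157 and to reads of 18 to 25 nt was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. Inserts under 18 nt were used only for library totals.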

Results

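Small RNA was profiled in trifoliate orange, in wild type trees and in a mutant that flowers early, each at the juvenile and the adult stage, to ask whether microRNAs take part in flowering. Levels are given as RPM, reads scaled to the clean reads of the library. Each of the 4 groups had 1 library, of between 17526615 and 21478087 clean reads, and no group had a replicate. Intervals in brackets are 95% counting intervals. The adult libraries came from lateral buds in spring and the juvenile ones from shoot meristems in early summer, so each stage difference below is also a difference of organ and season.

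All 4 libraries had the 2 length classes typical of plant small RNA, 21 nt (mostly microRNA) and 24 nt (mostly repeat-associated small interfering RNA). The 24 nt class held 36.6% of reads in the juvenile wild type, 37.9% in the adult wild type, 31.6% in the juvenile mutant and 33.0% in the adult mutant. The 21 nt class held 34.1%, 30.3%, 36.4% and 32.6% in the same order. Wilson 95% intervals were all narrower than 0.1 percentage points (for the first value, 36.63% to 36.67%). The ratio of 24 nt to 21 nt reads was lower in the mutant at both stages, at 0.868 against 1.07 in juveniles and 1.01 against 1.25 in adults. It was higher in adults in both genotypes. Over unique sequences the stage order turned: there were 6.52 and 6.14 unique 24 nt sequences per unique 21 nt sequence in the juvenile wild type and mutant, against 4.68 and 3.97 in the adults. The adult mutant library stood apart in long reads, with 5.07% of reads at 26 to 30 nt against 1.21% to 2.74% in the other 3 libraries. Fragments of 5.8S ribosomal RNA of 28 nt reached 679 RPM there against at most 38.7 elsewhere.

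**Figure D1:**
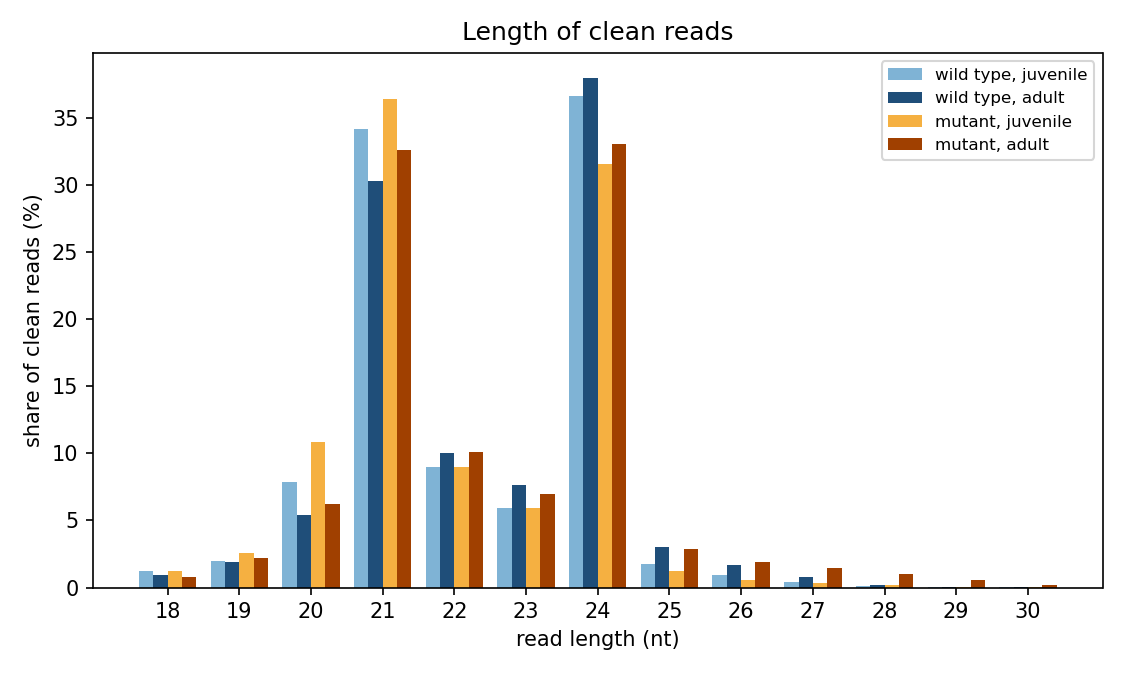
Share of clean reads (y axis, %) at each read length from 18 to 30 nt (x axis), 1 bar per library. The 24 nt bar is lower in each mutant library (31.6% and 33.0%) than in each wild type library (36.6% and 37.9%).

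Known plant families took 28.8% of reads in the juvenile wild type and 33.6% in the juvenile mutant, against 18.3% and 20.8% in the adults. Most of this was miR156/miR157, the family that represses SPL transcription factors and marks the juvenile phase, with 22.02% and 27.1% of juvenile and 12.2% and 14.2% of adult reads. Its most frequent sequence, UUGACGGAAGAUAGAGAGCAC, is 1 mismatch from the miR157 reference and alone made up 14.9% of juvenile wild type reads. The other families together kept a share between 6.17% and 6.76% in each library.

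The first comparison asked what differed between the stages within the wild type. The copper-related families were far lower in the adult library: miR408, which targets plantacyanin and other blue copper proteins, had 363 RPM in the juvenile and 1.997 in the adult library (log2 ratio -7.50, -8.03 to -7.03). miR397, which targets laccases, went from 1505 to 18.8 (log2 ratio -6.32, -6.48 to -6.16), and miR398, which targets copper/zinc superoxide dismutases, from 78.6 to 2.34 (log2 ratio -5.07, -5.55 to -4.62). The phase change pair lay on opposite sides: miR156/miR157 was lower in the adult (log2 ratio -0.86), and miR172, which targets AP2-like repressors of flowering, was higher (552 to 1615 RPM, log2 ratio 1.55, 1.52 to 1.58). Of 27 measured families, 7 were at 2-fold or more higher in the adult and 9 lower.

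By list, all 4 measured members of nutrient and copper homeostasis were lower in the adult wild type, miR169 (log2 ratio -1.96) with the 3 above. Their median of -5.70 lay at the 0.19 percentile of random lists of families of like level. All 3 members of the small RNA machinery list were higher: miR162, which targets DICER-LIKE1, at a log2 ratio of 2.14 (2.04 to 2.24), miR403, which targets ARGONAUTE2, at 1.34, and miR168, which targets ARGONAUTE1, at 1.07 (percentile 93.4), though miR168 fell below 2-fold with TMM factors (0.85) and scaled to reads outside miR156/miR157 (0.89). In auxin signalling 3 of 5 were lower, namely the trans-acting tasiARF (-3.52), miR167 (-2.41) and miR160 (-1.92), all directed at auxin response factors, and miR393, which targets the auxin receptors, was higher (1.19, but 0.97 with TMM factors). The median of that list was at the 20.4 percentile. The opposite strand of the miR160 hairpin did not share the fall, with 444 RPM in the juvenile and 856 in the adult wild type. In phase change and flowering 1 of 4 was higher, miR172 (percentile 89.5). In meristem and organ patterning 1 of 4 was lower, miR170/miR171 (-2.91), whose targets are GRAS regulators of meristems (percentile 62.1). The opposite strand of miR170/miR171 hairpins differed little, with 74.9 RPM in the juvenile and 63.8 in the adult wild type. The MYB-directed miR858 was higher, from 2.47 to 43.5 RPM (4.14, 3.74 to 4.57). In the citrus or woody lineage list miR3952 was higher (1.85) and miR479 lower (-2.30) of 4, and neither of the 2 measured members of the resistance gene list reached 2-fold. The opposite strand of miR3952 did not rise (228.2 to 200.1 RPM), and that of miR479 fell (56.3 to 9.36). Below the minimum of 10 RPM, miR472 of the resistance gene list went from 1.63 to 7.13 RPM in the wild type (2.13, 1.58 to 2.71). In the mutant it went from 1.42 to 8.51 (2.59, 1.98 to 3.25). miR1515 of that list, also below the minimum, had log2 ratios of -0.08 and -0.09.

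The same comparison in the mutant gave 5 families higher and 10 lower in the adult among 29 measured. miR397 (log2 ratio -7.21, -7.41 to -7.01), miR408 (-6.62, -7.05 to -6.22) and miR398 (-6.42, -6.93 to -5.96) again had the lowest ratios, followed by miR399, which acts in phosphate homeostasis and had 11.1 RPM in the juvenile and 0.226 in the adult mutant (-5.62, -7.51 to -4.24). The adult value of miR399 is 4 reads, and with a pseudocount of 1 RPM its log2 ratio was -3.30. All 6 measured members of nutrient and copper homeostasis were lower, with miR827 (-2.37) and miR169 (-2.29), at the 0.045 percentile of random lists. miR172 was higher (1.68, 1.65 to 1.71) and miR156/miR157 lower (-0.93). In auxin signalling miR167 (-2.98) and tasiARF (-2.42) were lower and miR393 was higher (2.27) of 4, at the 25.7 percentile. miR168 was the only 1 of 3 small RNA machinery members at 2-fold (1.11, percentile 88.4), and with TMM factors (0.83) or scaled to reads outside miR156/miR157 (0.87) it too fell below. miR162 had a log2 ratio of -0.24 in the mutant. miR858 (2.54) and miR530 (1.38) were higher, and miR3951 (-1.51) and miR170/miR171 (-1.37) were lower, but by less than 2-fold scaled to plant-family reads (-0.82 and -0.68). The opposite strand of miR170/miR171 hairpins had 86.3 RPM in the juvenile and 79.8 in the adult mutant. That of miR3951, which outnumbered the mature strand, had 695 RPM in the juvenile and 481 in the adult mutant (log2 ratio -0.53).

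**Figure D2:**
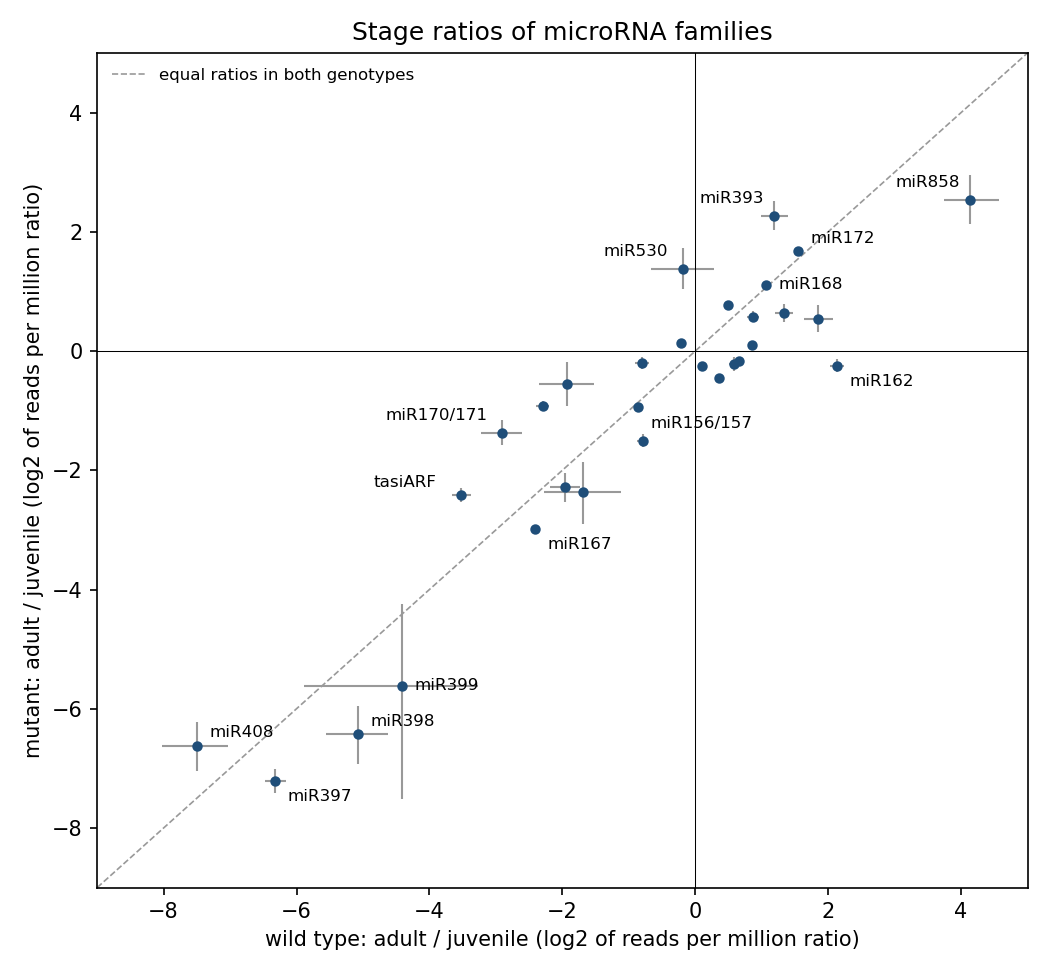
Adult to juvenile log2 ratio of each of 30 microRNA families in the wild type (x axis) and the mutant (y axis), with 95% counting intervals as bars and 1 library per group. miR397, miR398, miR399 and miR408 lie below -4 on both axes, miR172 lies at 1.55 and 1.68, and miR162 lies at 2.14 in the wild type and -0.24 in the mutant.

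Across the 30 families the stage ratios of the genotypes ran together (Pearson r = 0.92, Spearman rho = 0.87, over families, which are not independent replicates), and 23 of 30 had the same sign. The counts at 2-fold depend on scaling. The median stage log2 ratio, 0.10 in the wild type and -0.24 in the mutant, became 0.75 and 0.45 scaled to plant-family reads, and -0.12 and -0.52 with edgeR TMM factors. Scaled to plant-family reads 13 families were higher and 9 lower in the adult wild type, and 9 and 8 in the mutant. With TMM factors these were 5 and 12, and 4 and 12. The ratios of miR397, miR398 and miR408 stayed below -4.4 and those of miR172 above 1.3 under every scaling tried. Those of miR156/miR157 stayed negative but ran from -1.08 to -0.21 in the wild type and from -1.21 to -0.25 in the mutant. The ratios smallest in size came from scaling to plant-family reads. Most of those reads were miR156/miR157 itself, so this scaling shrinks its ratio by construction. The same scaling raises the adult to juvenile ratio of each other family.

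The additive edgeR fit takes as its error the disagreement of the genotypes, shared across the 30 families and not measured for each alone. Its small p-values rest on that sharing and not on replicates. In this fit 11 of 30 families passed an adjusted p of 0.05 for stage, 4 that rose in adults and 7 that fell. DESeq2 called 18 (9 higher and 9 lower), and the edgeR fit without the covariate 15 (4 higher and 11 lower). Each of the 11 families of the main fit had the same direction in both genotypes. This adds no support, because the fit favours families in which the genotypes agree. In that fit the log2 change was -6.76 for miR397 (SE 0.546, edgeR adjusted p = 7.62e-12), -7.05 for miR408 (SE 0.905, edgeR adjusted p = 1.08e-07), -5.74 for miR398 (SE 1.11, edgeR adjusted p = 8.11e-05) and -4.96 for miR399 (SE 1.27, edgeR adjusted p = 0.00206). It was -2.69 for miR167 (SE 0.241, edgeR adjusted p = 5.01e-11), -2.97 for tasiARF and -0.90 for miR156/miR157 (SE 0.125, edgeR adjusted p = 4.13e-07). miR172 rose by 1.61 (SE 0.392, edgeR adjusted p = 0.00136), with miR858 (3.33), miR168 (1.09) and miR165/miR166 (0.64), which targets class III HD-ZIP regulators of leaf polarity. By list, 4 of 6 members of nutrient and copper homeostasis passed, 2 of 5 of auxin signalling, 2 of 4 of phase change and flowering, 1 of 4 of meristem and organ patterning, 1 of 3 of small RNA machinery, the 1 MYB member, 0 of 2 of the resistance gene list and 0 of 5 of the citrus or woody lineage. Adjusted over the list alone, the counts were the same for each list. Of the 11 calls 8 held under each of 4 other fits. The exceptions were miR156/miR157, which missed with DESeq2 (adjusted p = 0.127, against 2.29e-06 to 0.00603 in the other 3 fits), miR165/miR166, which missed with TMM (edgeR adjusted p = 0.102) and without the covariate (edgeR adjusted p = 0.0593; 0.00398 and 0.0439 with DESeq2 and the relaxed filter), and miR168, which missed with the relaxed filter (edgeR adjusted p = 0.0764, against 1.37e-05 to 0.0216 in the other 3 fits).

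Within some families the stage ratios of single sequences lay apart. The main miR167 sequence, UGAAGCUGCCAGCAUGAUCUGA, had 14349 RPM in the juvenile and 2634 in the adult wild type, and 13342 and 1131 in the mutant. The shorter UGAAGCUGCCAGCAUGAUCUA went the other way, from 220.2 to 327.2 and from 188.0 to 561.2. Counted on exact references alone, which leaves out the main sequence, the miR167 ratio was therefore positive, at 0.27 in the wild type and 0.95 in the mutant. For miR172, AGAAUCUUGAUGAUGCUGCAU was higher in adults (log2 ratio 1.82 and 1.93 in wild type and mutant) and AGAAUCUUGAUGAUGCUGCAA was lower (-1.57 and -1.09). The exact miR156 sequence UGACAGAAGAGAGUGAGCAC had steeper ratios (-1.66 and -2.53) than the main miR157-like sequence (-0.68 and -0.64).

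The phase change pair was also set against each other within each library, which needs no scaling. There were 399 reads of miR156/miR157 per read of miR172 in the juvenile wild type (392 to 406) and 455 in the juvenile mutant (446 to 464). In adults the ratio was 75.2 (74.4 to 76.1) and 74.2 (73.4 to 75.02). The stage difference was thus over 5 times in each genotype, while the adult genotypes had overlapping intervals and the juvenile mutant lay above the juvenile wild type. With exact references only the ratios were much lower (27.9 and 38.0 in juveniles, 2.53 and 1.75 in adults), and the adult mutant then lay below the adult wild type.

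**Figure D3:**
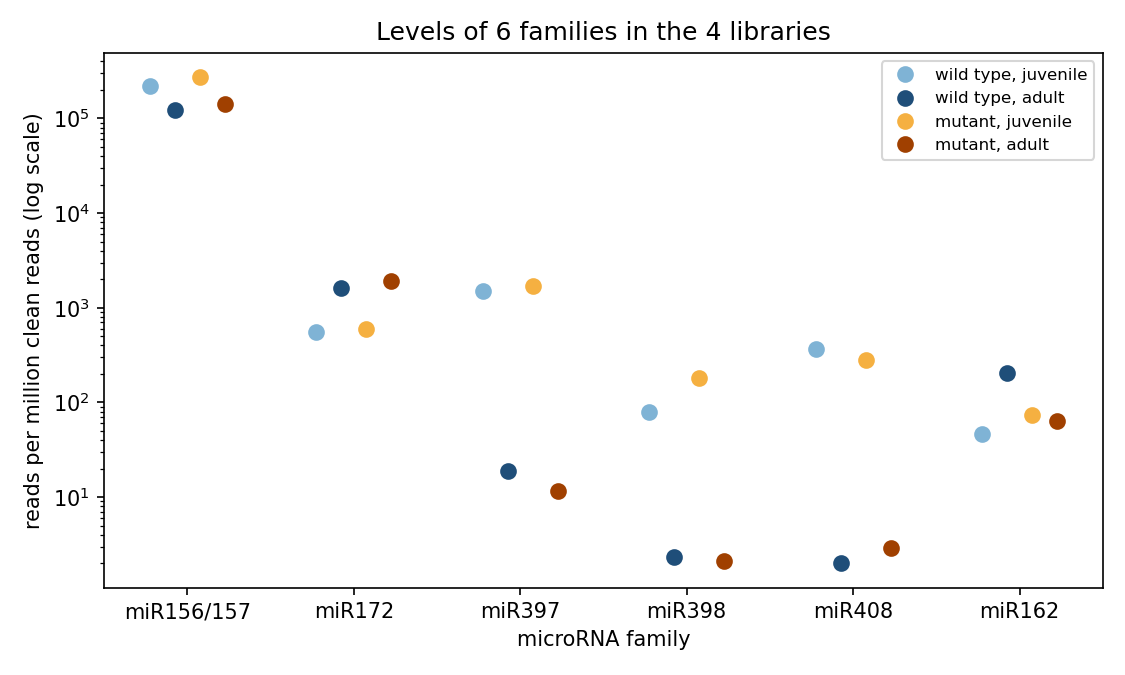
RPM (y axis, log scale) of 6 microRNA families (x axis) in the 4 libraries, 1 point per library. miR397, miR398 and miR408 are lower in both adult libraries, miR172 is higher in both, and miR162 stands out in the adult wild type at 202.2 RPM.

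The comparison of mutant with wild type in juveniles found few differences of size. Of 28 measured families 1 was at 2-fold or more, miR398, with 179 RPM in the mutant and 78.6 in the wild type (log2 ratio 1.19, 1.10 to 1.27), and none was lower. Below the minimum of 10 RPM, miR394 had 1.47 in the mutant and 8.94 in the wild type (-2.60, -3.24 to -2.02). In adults it had 0.96 and 3.54 (-1.88, -2.75 to -1.09). Scaled to plant-family reads miR398 was at 0.96 and no family reached 2-fold. The opposite strand of the miR398 hairpin did not share this direction, with 2567 RPM in the mutant and 3493 in the wild type. miR164, which targets NAC regulators of organ boundaries, came next at a log2 ratio of 0.99 (0.96 to 1.03). miR156/miR157 was slightly higher in the mutant (0.30), and miR172 had a log2 ratio of 0.11, which became -0.11 scaled to plant-family reads and -0.03 scaled to reads of 20 to 22 nt. None of the lists had a measured member at 2-fold except nutrient and copper homeostasis with miR398 (1 of 6, percentile 92.6). The other list medians lay between the 8.91 percentile (auxin signalling) and the 65.2 percentile (phase change and flowering), and no MYB member was measured.

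In adults 5 of 25 families differed by 2-fold or more between mutant and wild type. The adult mutant library also held more reads of 26 to 30 nt (5.07% against 2.74% in the adult wild type). Whether this bears on the ratios was not tested. miR530 (14.2 against 3.88 RPM, log2 ratio 1.87, 1.48 to 2.28) and miR170/miR171 (14.3 against 5.76, 1.31, 0.98 to 1.66) were higher in the mutant. miR162 (62.9 against 202.2, -1.68, -1.78 to -1.59), miR3948 (61.5 against 161.0, -1.39, -1.49 to -1.29) and miR858 (18.9 against 43.5, -1.20, -1.39 to -1.01) were lower. miR156/miR157 had a log2 ratio of 0.22 and miR172 of 0.24; the first turned to -0.29 on exact references, since the exact miR156 sequence was lower in the adult mutant (-0.30) and the main miR157-like sequence higher (0.26). By list, 1 of 4 in meristem and organ patterning was higher, 1 of 3 in small RNA machinery and the 1 measured MYB member were lower, and the citrus or woody lineage had 1 higher and 1 lower of 5. None of the 4 in phase change and flowering, 4 in auxin signalling, 2 in nutrient and copper homeostasis and 2 in the resistance gene list reached 2-fold. List medians lay between the 5.59 percentile, for miR858 alone, and the 89.5 percentile, for auxin signalling. Both miR530 and miR170/miR171 had under 15 RPM in each adult library. At a minimum of 50 RPM neither of them nor miR858 was measured, which left miR162 and miR3948 of 17 families, and miR3948 was below 2-fold without mismatches (-0.98).

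The genotype ratios in juveniles and in adults did not run together across the 30 families (Pearson r = -0.17, Spearman rho = -0.26), with 12 of 30 of the same sign. For 11 families the genotype ratio differed by 2-fold or more between the stages, 6 toward higher values in the adult mutant and 5 toward lower. The additive edgeR fit found 0 of 30 families with a genotype effect at an adjusted p of 0.05, with 1 at an unadjusted p under 0.05 in edgeR and 2 in DESeq2, which also called 0. A genotype effect was not simulated, so the size of change that this fit could have called is not known. The design cannot tell a family that responds to genotype at 1 stage only from a library that varies on its own.

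Over single sequences the additive edgeR fit called 369 of 5452 for stage, 208 higher and 161 lower in adults. With TMM factors the count was 373, split 162 higher and 211 lower. DESeq2 called 1380 (616 higher and 764 lower), and the fit without the covariate 1077 (679 and 398), so neither the count nor its balance is firm. The 369 calls of the main fit included 12 sequences of miR156/miR157, 6 of miR397, 4 of miR408, 7 of the opposite strand of the miR408 hairpin and 4 of that of miR398, all lower in adults. For miR172, 1 sequence was called higher in adults and 1 of the opposite strand lower. Among the sequences named by rule, the largest fall was that of UCAAGGACAUAGAGGCAUUUA, which matched no reference (log2 change -7.58, SE 0.830, edgeR adjusted p = 0.0450). Then came CGGGGAACAGGCAGAGCAUGG and its shorter form CGGGGAACAGGCAGAGCAUG from the miR408 opposite strand, UCAUUGAGUGCAGCGUUGAUG of miR397 and AUGCACUGCCUCUUCCCUGGC of miR408, with log2 changes of -6.85, -6.74, -6.73 and -6.71. The largest rises were in sequences that matched no reference, CAAGUCAUUAGAGAACUGCCG (log2 change 6.48, SE 0.312, edgeR adjusted p = 0.0394), UCAAUUCUAGUAGAAUUACGG (6.10), UUGAUCGGGUAGAAUAACGCCAUG (6.04), UAUACAAAUACGUCGGCAUUC (5.36) and GAGUGGGUAUGCGGGCUUCUUUCGA (4.19). The adjusted p of these 10 lay between 0.0394 and 0.0492, close to the threshold. For genotype the edgeR fit called 0 of 5452, with 290 at an unadjusted p under 0.05, about the share that chance alone gives, while DESeq2 called 54. Only the stage effect was simulated, and there 0 of 200 changes of 4-fold were called. The 0 genotype calls therefore cannot exclude changes of that size.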

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

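The tests of scaling and of opposite strands in the closing paragraphs were chosen after the copper-related ratios were seen, as were the test of paired sequences, the split of arthropod reads by genotype and the conditions that picked the 7 families; the tests of GC content and of arthropod and vertebrate reads were set before their results were seen.

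For 7 families the mutant to wild type ratio pointed one way in juveniles and the other way in adults, with both counting intervals clear of 0 and a difference of at least 2-fold. With 1 library per group the difference was not tested. miR162, which targets DICER-LIKE1, differed by -2.38 on the log2 scale, from 0.70 in juveniles to -1.68 in adults, because its adult level was above its juvenile level in the wild type only. miR3952 differed by -1.30 (0.55 to -0.76). The other 5 moved the opposite way: miR170/miR171 by 1.54 (-0.23 to 1.31), miR479 by 1.37 (-0.69 to 0.68), miR160 by 1.37 (-0.62 to 0.75), tasiARF by 1.10 (-0.30 to 0.81) and miR393 by 1.08 (-0.53 to 0.55). miR160 had 3.42 and 5.75 RPM in the adult wild type and mutant, below the minimum of 10 for the adult comparison. Not all opposite strands turned likewise. In juveniles and adults, that of miR160 was lower in the mutant (427 and 630 RPM against 444 and 856). Those of miR170/miR171 (86.3 and 79.8 against 74.9 and 63.8) and miR3952 (230.2 and 346 against 228.2 and 200.1) were higher. Those of miR479 (35.1 and 15.9 against 56.3 and 9.36) and miR393 (3.87 and 8.57 against 5.26 and 5.71) turned as the mature strand did. For miR162 and tasiARF it was not above 3 times the reversed background.

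Reads like the animal microRNA let-7 were found in data that no comparison used. With each reversed reference at 0, let-7 had 210 reads over the 2 juvenile libraries and 5 over the adult ones. Whether they come from arthropods living on the plants cannot be told apart, because the genotypes disagree. The 6 references found in arthropods and not in vertebrates had 827 reads in the juvenile and 74 in the adult libraries, but 748 of the 827 were in the juvenile wild type, 480 of them of miR-275, against 4 in the adult wild type. In the mutant they had 79 juvenile and 70 adult reads (ratio of rates 1.09, 0.780 to 1.53), while let-7 had 99 and 3. The most frequent animal reference, miR-1, which arthropods and vertebrates share, had 1234 and 4277 reads in the juvenile wild type and mutant against 66 and 448 in the adults. Human or other vertebrate RNA from handling is argued against, since none of 6 vertebrate-only references had more than 1 read in the juvenile libraries. No biological explanation within the plant was tested.

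The copper-related families miR397, miR398 and miR408 were far lower in both adult libraries. Scaling is argued against, as the highest of the 6 log2 ratios over all scalings was -4.42. A loss of the mature miR398 and miR408 in library making as the whole cause is argued against by the opposite strands of their hairpins. These have other bases and were lower in adults too, with a highest log2 ratio of -2.43 (miR398 in the wild type). The miR408 opposite strand had 8210 and 163 RPM in the juvenile and adult wild type. For miR398 the mature strand fell further than the opposite strand (-5.07 against -2.43 in the wild type, -6.42 against -3.24 in the mutant). An added loss of mature miR398 can therefore not be told apart. For miR397 no part of such a loss can be told apart, because its opposite strand had 61 reads over the 4 libraries against 58 for the reversed background. GC content is argued against, since other families in the same range had a median of 0.43 in the wild type (quartiles -1.68 and 1.02) and -0.22 in the mutant (-1.60 and 0.63), with the 3 families below the lower quartile in each. The lowest of the others measured were tasiARF at -3.52 in the wild type and miR399, with 4 adult reads, at -5.62 in the mutant. In the wild type miR399 was below the minimum of 10 RPM and so was not among them. It had 6 adult reads and a log2 ratio of -4.42 there. Organ, season and the nutrient supply of potted or field plants stay open as untested explanations.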

How the results depend on the processing

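Scaling to reads outside miR156/miR157 and to reads of 18 to 25 nt was chosen after seeing the data; all other settings were fixed before the data were examined. No paired analysis by replicate was possible because each group has 1 library; the additive fit takes the other factor as its block, and without it 15 families were called for stage in place of 11. Leaving out a library leaves the additive fit no residual degrees of freedom. The wild type stage comparison and the juvenile genotype comparison do not use the adult mutant library. Of 421 values of single families under the alternatives, 270 stayed the same within counting error or on their side of the threshold, 139 moved without changing sign, 4 lost an adjusted p under 0.05 and 8 reversed. Part of the 270 was fixed in advance, since a minimum of 1 or 50 RPM cannot change the ratio of a family. Of 126 counts and ratios 82 stayed the same. The cause of the other changes was not tested, except where an alternative removes families or reads by its own construction.

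Some scalings ended calls at 2-fold: miR168 with TMM factors and with reads outside miR156/miR157 (0.85 and 0.89 in the wild type, 0.83 and 0.87 in the mutant), miR393 in the wild type with TMM factors (0.97), and miR398 in juveniles (0.96), miR3951 (-0.82) and miR170/miR171 (-0.68) in the mutant with plant-family reads. Most plant-family reads were of miR156/miR157, so that scaling largely follows this family. Scaled to plant-family reads, juveniles had 0 families higher in the mutant, adults 5 lower in the mutant, and 13 (wild type) and 9 (mutant) families were higher in adults; the juvenile genotype ratio of miR172 turned to -0.11, and to -0.027 scaled to reads of 20 to 22 nt. With TMM factors, and scaled to reads outside miR156/miR157, 2 families were higher in the juvenile mutant, 2 also as members of the lists. Exact references left 16 or 17 families: 0 were higher in the adult mutant, 4 lower in the adult wild type, and 2 higher and 5 lower with stage in the mutant. Without mismatches but with end offsets these were 1 higher and 1 lower in the adult mutant, 4 lower with stage in the wild type, and 3 higher and 5 lower in the mutant. The adult genotype ratio of miR156/miR157 turned to -0.29 and -0.33 under these matchings, and the stage ratio of miR167 to 0.27 and 0.049 in the wild type and 0.95 and 0.73 in the mutant. A minimum of 1 RPM gave 1 family lower in the juvenile mutant and 5 lower in the adult mutant; one of 50 gave 0 higher in the adult mutant, 4 higher in the adult wild type, and 2 higher and 6 lower with stage in the mutant. With exact references 7 of 24 families differed by 2-fold between stages in their genotype ratio.

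DESeq2 called 18 families and 1380 sequences for stage and 54 sequences for genotype. Without the covariate 1077 sequences were called for stage, and 12529 of 66707 with the relaxed filter. The ratio of 24 to 21 nt over unique sequences was 6.52, 4.68, 6.14 and 3.97 in the juvenile wild type, adult wild type, juvenile mutant and adult mutant. Over reads, with sequences read once left out, it was 0.820, 0.991, 0.632 and 0.787. Limiting lengths to 18 to 30 nt cannot move it. The ratio of miR156/miR157 to miR172 was 27.9, 2.53, 38.0 and 1.75 with exact references and 57.0, 7.05, 71.6 and 4.75 with end offsets allowed. Depth limits miR399, with 4 reads in the adult mutant (-3.30 with a pseudocount in place of -5.62), and miR398 and miR408, with 35 to 51 reads in each adult library.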

Other observations

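The count of paired sequences in this part was chosen after the pattern was seen, and so were the minimum of 5 split pairs needed to decide it, the counts of sequences seen in some libraries alone and the unmatched sequence set beside miR398, with the test of size selection and the counts of linked groups. Reads outside the known families held further stage differences. One of the most frequent unmatched sequences, UCUCAGGUCGCCCCUGUGGGA, begins with the last 16 bases of the main miR398 sequence UGUGUUCUCAGGUCGCCCCUG, and at 6143 RPM in the juvenile wild type it was far above miR398 itself. It had 173.7 in the adult wild type, 1527 in the juvenile mutant and 135.5 in the adult mutant (stage log2 ratios -5.14 and -3.49), so in juveniles it was lower in the mutant while miR398 was higher. The opposite strand of miR408 also outnumbered the mature strand, with 8210 and 8293 RPM in the juvenile libraries against 363 and 283. Other frequent sequences with no reference match differed less, such as UCAGGAUAUGGUUUUGAUAAU (5570, 8260, 4906 and 7852 RPM in juvenile wild type, adult wild type, juvenile mutant and adult mutant) and UGGUAUGGGUGAGUAGGGAAG, which was higher in adults (1002 and 849 in juveniles, 4126 and 2975 in adults). Of the sequences that edgeR called for stage, 207 of the 208 higher and 120 of the 161 lower in adults matched no reference. Of all 5452 tested, 5073 matched none. Those lower in adults thus held a smaller share of unmatched sequences than the tested set. They included 27 of 237 tested family sequences and 12 of 38 tested opposite strands.

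Sequences seen at 2 or more RPM in 2 libraries and at 0.2 or less in the other 2 followed stage and hardly genotype. There were 649 seen in the adult libraries alone and 541 in the juvenile libraries alone, of 66707 searched. There were 40 in the mutant libraries alone and 1 in the wild type alone, against 0 and 2 for the remaining splits. All 40 were 28 to 30 nt long, none of 21 or 24 nt, and they fell into 18 groups linked by shared stretches. The longest reads differed between the genotypes too: those over 30 nt had 37.1 and 80.9 RPM in the juvenile and adult wild type against 148 and 570 in the mutant, and 5.8S ribosomal fragments of 29 nt had 0.792 and 1.20 against 17.2 and 569. Shorter ones did not follow in juveniles: reads of 26 to 30 nt were 1.41% in the wild type and 1.21% in the mutant, and 5.8S fragments of 26 nt had 712 and 236 RPM. Whether the 40 go with the mutation or with these longer reads was not tested. Across sequences the log2 levels (0.5 RPM added) of the juvenile libraries had a Pearson r of 0.91 and those of the adult libraries 0.87, against 0.57 to 0.64 between stages; sequences are not independent replicates.

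A further pattern concerned the adult mutant library alone. Of 764 sequences with a mean of at least 50 RPM, 19 were at least 4-fold lower there than in each other library, with 0.5 RPM added to each value, against 0 for the juvenile wild type, 2 for the adult wild type and 5 for the juvenile mutant. Linked by shared stretches the 19 formed 13 groups, against 2 and 5 groups for the latter. At lower levels, 104 sequences had at least 2 RPM in each other library and at most 0.2 in the adult mutant (61 groups), against 0, 5 and 10 (5 and 7 groups for the last 2). UCGCAGGAGCUUUCUACGGUU had 966 to 1142 RPM in the other libraries and 18.0 in the adult mutant, and UGCUGAUUUAGAAGAUUUUGC had 288 to 328 and 3.27. Size selection, which acts on length, is argued against for the 19: their lengths were 21, 22 and 24 nt, and the share of reads at each was no lower in the adult mutant than in the lowest other library (lowest log2 ratio 0.065). A candidate explanation is a base difference between the plants sampled, but 1 of 409 pairs of frequent sequences 1 base apart was split in this way, too few to decide it: UCCGACGGUGGAAGCAAUUAUG had 99.7%, 97.3% and 99.8% of its pair's reads in the other libraries and 4.96% in the adult mutant, where UCCGACGGUGGAAGCAAUUGUG (A20G, position counted from the 5′ end) prevailed. A change that goes with the mutation at the adult stage stays open and was not tested.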
